A study of Drosophila melanogaster with 3 samples.

How the data were processed

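Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, collected over 0 to 24 hours of age. The flies carried a transgene in which the RA isoform of chif (chiffon) is fused at its C terminus to enhanced green fluorescent protein, and the immunoprecipitation used an antibody against GFP, per the labels. The labels give sonication as the fragmentation method and a fragment range of 200 to 800 bp. They describe 3 biological replicates of this 1 group and no group of another genotype or treatment, so every comparison is between classes of genomic regions or genes within the group, and the spread between the 3 replicates is the error each value is set against.

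The deposited files are narrowPeak region lists in the genome builds dm6 and dm3. Per the deposited file listings, each replicate has a relaxed list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure, 1 further relaxed list was made from the alignments of all 3 replicates together with a control alignment, and the IDR list was derived from these 4 lists. The relaxed replicate lists hold 30000 regions each, the pooled list 25066 and the IDR list 3684 in dm6. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' score, with no stated scale, and was used only to rank and describe regions within a list. The −log10 q of each region is likewise the authors' deposited value. The remaining value used, the offset of the summit from the start of its region in bp, was taken from the authors' lists. No read counts accompany the lists, so the sequencing depth of the replicates is unknown and no interval that needs it is given. No control or untagged library was analysed here.

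All coordinates are dm6 and are given 1-based. The chromosome lengths of the reference genome sequence were compared with every dm6 list, and 0 regions ended beyond the end of their chromosome. The dm6 lists hold regions on 2L, 2R, 3L, 3R, 4 and X alone, so Y could not be described as planned. Gene models were those of Ensembl release 115 for the assembly BDGP 6.54, with transposable element entries left out. A start site is the 5' end of any annotated transcript. Comparisons used start sites of 13945 protein-coding genes on these chromosomes, and a gene was called occupied where a summit lay within 500 bp of a start site. Each summit received 1 annotation class in the order promoter (within 500 bp of a protein-coding start site), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic.

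The background for the IDR peaks was the 20865 regions of the pooled list that overlap no IDR peak, called lower-ranked regions here. Each value was also computed on the 3684 regions of highest signal value in each replicate, against the remaining regions of the same replicate that overlap none of them. These replicate values give mean, SD and n = 3. Regions and genes are not replicates, and genes that share a peak are not independent, so the direction in each replicate is given beside the p-values.

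Overlap between lists needed at least 1 bp. Observed overlap was compared with 1000 random placements of the regions on their own chromosomes (permutation test, one-sided). Shares were compared with Fisher's exact test, two-sided, with an odds ratio and its 95% Wald interval, adding 0.5 to each cell where a cell was 0. Benjamini-Hochberg adjustment was applied over 23 gene lists and, separately, over 13 sequence motifs. A motif was counted where its consensus matched either strand in the 201 bp window centred on a summit. The threshold was 0.05. A gene was classed as head to head where a protein-coding start site on the other strand lay within 500 bp of 1 of its own. The rule did not require the genes to point away from each other, so genes with overlapping 5' ends were counted too.

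The gene lists cover DNA replication, cell cycle regulators, SAGA and ATAC coactivator subunits, cytosolic and mitochondrial ribosomal proteins, proteasome subunits, oxidative phosphorylation, translation factors, splicing factors, replication-dependent histones, insulator and housekeeping promoter factors, Hox and segmentation genes, developmental signalling components, early zygotic cellularization genes, neuronal, muscle, germline, hemocyte and tracheal genes, cuticle proteins, chemosensory receptors, chorion and vitelline membrane proteins, and heat shock proteins. Of the listed symbols, 23 did not match the annotation and were left out, several of them older names. The lists, motifs, tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule names chif, the 20 genes with the strongest IDR peak within 500 bp of their start site where the peak overlaps the highest regions of all 3 replicates, up to 4 members of each list by signal value, any occupied member of the DNA replication and the SAGA and ATAC lists, and the 5 strongest IDR peaks over 1000 bp from every annotated start site.

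Alternatives were promoter windows of 250 and 1000 bp, the stronger 1842 of the IDR peaks, other overlap criteria, 1842 or 7368 regions per replicate, motif windows of 50 or 200 bp either side, random positions (10 per peak) or promoters without a peak as background, start sites of all annotated genes, assignment of each peak to the nearest start site alone, and leaving out each replicate in turn. For the last, the IDR list was replaced by regions found among the highest 3684 of both other replicates. The overlap alternatives used 100 random placements each. A background of lower-ranked regions matched to the IDR peaks in GC content within 20 bins, and the left-out replicates for the annotation classes, were added after seeing the data.

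Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The measures were tested on simulated data. For gene list occupancy, over 13945 genes, 3 of 3 lists with peaks placed at 60% of their promoters were called and 0 of 20 unchanged lists were. For the replicate overlap, 70.8% was measured where 70% of 3684 regions were shared and 2.63% where nothing was shared. For the motif share, 20.5% of 3684 windows carried a motif placed in 20%, and 0 of 12 other motifs were called. For the promoter share, 48.1% was measured against 47.4% from the placement. Sensitivity at list shares below 60% and motif shares below 20% was not measured. Both sets of motif windows were random positions, so no difference in GC content was simulated.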

Results

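The data describe where the tagged Chiffon protein was recovered on chromatin of 0 to 24 hour Drosophila embryos. Chiffon is the fly relative of Dbf4, the regulatory subunit of the replication kinase Cdc7. The same gene also encodes a part that binds the histone acetyltransferase Gcn5, and it is needed for chorion gene amplification in ovarian follicle cells. The tag sits at the C terminus of the RA isoform, so tagged products include that end. The data do not show how much of the rest of the protein they carried. The group comprised 3 biological replicates. Their relaxed lists held 30000 regions each, the pooled list 25066 and the authors' IDR list 3684 peaks with a median width of 396 bp. The dm3 counterparts held 30000 regions per replicate, 21005 in the pooled list and 3716 in the IDR list. All 3684 dm6 IDR peaks were among the 3684 pooled regions of highest signal value, down to a signal value of 92.3.

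The tagged gene itself carried 1 of the strongest peaks. chif (FBgn0000307) lies on the minus strand of 2L at 16342430 to 16352628, with annotated start sites at 16352628 and 16350283, and the neighbouring annotation Hyls1 shares its outer exons. The strongest region of the locus spanned 16351059 to 16351405 in an intron of both genes, 992 bp from the nearest start site, with a signal value of 1282 and rank 14 of the IDR list. The overlapping regions ranked 30, 12 and 4 in replicates 1, 2 and 3. Another IDR peak at 16350156 to 16350551, with its summit 71 bp from the inner chif start site, had a signal value of 219.9. The region at 16351277 to 16351672 had 113.1, and that at 16353104 to 16353499, by the start site of the next gene CG4455, had 94.9. The flies also express chif from a transgene, so these peaks are read apart from the others.

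**Figure D1:**
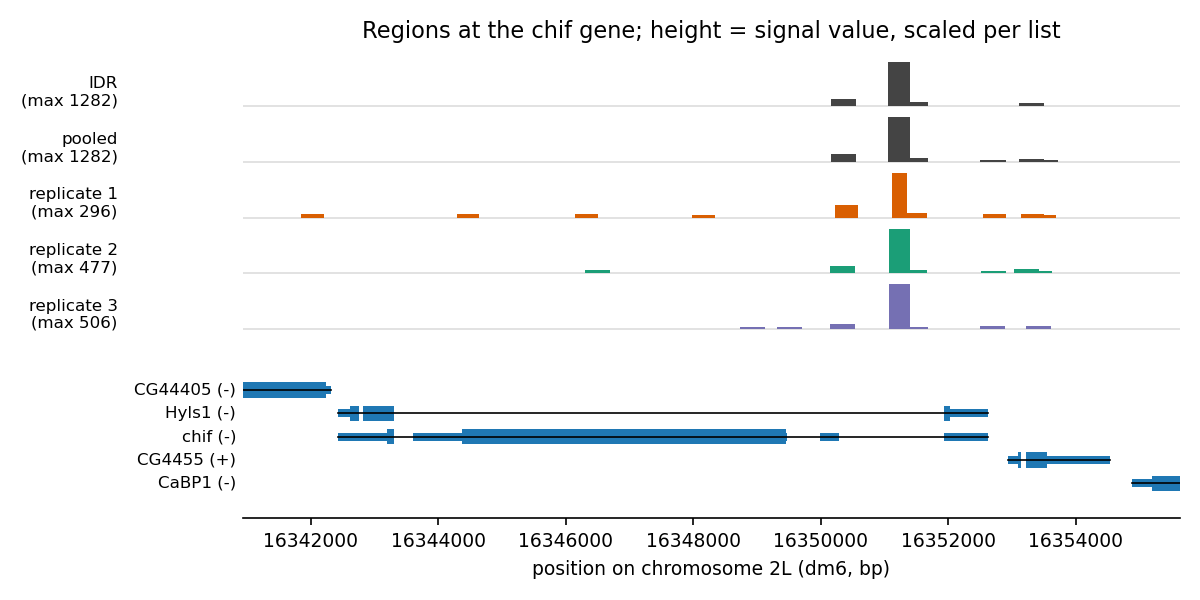
Regions of the IDR list, the pooled list and the 3 replicate lists at chif on 2L (x axis, dm6 position in bp). Bar height is the authors' signal value scaled to the highest region of each list, and thick and thin blue boxes are coding and other exons. The region in the intron, with a signal value of 1282 in the IDR list, stands highest in all 3 replicates.

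The strongest regions recurred between the replicates, with replicate 1 standing somewhat apart. Replicates 2 and 3 shared 74.89% and 75.03% of their 3684 highest regions, replicates 1 and 2 shared 66.4% and 67.2%, and replicates 1 and 3 shared 64.3% and 65.4%, counted from each side. The mean over the 3 pairs was 68.9% ± 5.38 (SD, n = 3 pairs). Random placements gave 1.97% to 2.07% on average and 2.96% at most, and the permutation p of 0.000999 in every pair is the smallest that 1000 placements can give. Across overlapping regions, which are not independent replicates, Spearman's rho of the signal values lay between 0.644 and 0.737. The region at rank 3684 had a −log10 q of 0.735 in replicate 1, against 2.69 in replicate 2 and 2.91 in replicate 3.

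Of the 3684 IDR peaks, 2178 (59.1%) overlapped the highest regions of all 3 replicates, 956 those of 2 replicates, 514 those of 1 and 36 those of none. By replicate the share was 75% in replicate 1, 85.2% in replicate 2 and 83.0% in replicate 3, a mean of 81.1% ± 5.37 (SD, n = 3). Replicate 1 alone was missing for 505 peaks, replicate 2 alone for 185 and replicate 3 alone for 266. Among the stronger 1842 peaks, 93.7% were found in all 3 replicates.

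Promoters were more frequent among IDR peaks than among lower-ranked regions. Summits of 1641 peaks (44.5%) lay within 500 bp of a protein-coding start site, against 22.5% of 20865 lower-ranked regions and 11.4% of random positions. The odds ratio against lower-ranked regions was 2.77 (95% interval 2.58 to 2.98, Fisher's exact test, p = 3.19e-160). The same share was 41.1%, 45.0% and 43.4% of the highest regions of replicates 1, 2 and 3, a mean of 43.2% ± 1.96 (SD, n = 3), and 20.4% ± 5.87 of their lower-ranked regions. All 3 replicates had the higher share among the highest regions, with odds ratios of 4.42, 2.69 and 2.40. The difference was larger than the spread between replicates. The share was 61.0% among the 100 strongest IDR peaks and 41.03% among ranks 2001 to 3684. The promoter summits lay mostly upstream of the start site, at a median of -97 bp (quartiles -193 and -36 bp), and 84.5% were on the upstream side, against 51.4% of lower-ranked promoter summits. The medians in the replicates were -90, -98 and -91 bp. Against random positions the odds ratio was 6.22.

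The 20 genes with the strongest promoter peaks found in all replicates came from varied functions. The strongest was CG14100 (FBgn0036889, 3L 19590445 to 19590801, signal value 2044, summit at -103 bp), followed by px, a nuclear protein gene needed for wing vein patterning (2R 22514139 to 22514472, 1673, -204 bp), and Ugalt, which encodes a UDP-galactose transporter (X 2703714 to 2704067, 1571, -45 bp). CG1888 (2R 9547026 to 9547344) followed with 1440. Chro, which encodes the interband and spindle protein Chromator, had a summit at 99 bp downstream of its start site (3L 22878730 to 22879089, 1409). The gene for the mitochondrial ribosomal protein mRpL41 (2R 15217596 to 15217925) had 1406, Art3, an arginine methyltransferase gene (3R 15229368 to 15229709), had 1388, and the Polycomb group gene ph-p (X 2137198 to 2137540) had 1372 with its summit at -480 bp. Signal values of PNPase, CenG1A, Tcs5, CG31145 and CG9147 ran from 1227 down to 1001. Those of Sox14, CG18549, Shc, GstE13, CG5098, Pal1 and CG8320 ran from 999.8 down to 874. Each of these 20 peaks ranked 63 or higher in each replicate, 19 of the 20 summits lay within 250 bp of the start site, and 16 lay upstream.

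Peaks far from start sites were nearly as numerous, with 1575 IDR summits (42.8%) over 1000 bp from every annotated start site. The strongest peak of the whole list was 1 of them. It lay in an intron of ush, which encodes the GATA cofactor U-shaped, on 2L at 480899 to 481272 and 1401 bp upstream of cbt, a zinc finger factor gene, with a signal value of 2129 and ranks 2, 1 and 1 in the replicates. The next was intergenic, on 2R at 13035166 to 13035484, 11924 bp from the start site of CG13323 (1461). The others lay in introns of CG11050 (2L 6612537 to 6612895, 1442) and CG32772 (X 4910212 to 4910534, 1011), and upstream of DNAlig3 (3R 12402981 to 12403284, 942.4).

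Coding exons outside promoters and UTRs were nearly devoid of IDR summits. Of the 3684 summits, 7 (0.19%) lay in coding exons outside promoters, against 18.1% of lower-ranked regions and 13.4% of random positions. Among the highest regions of the replicates the share was 5.0% in replicate 1, 0.353% in replicate 2 and 0.163% in replicate 3, and among their own lower-ranked regions 22.3%, 15.0% and 14.3%. Each replicate had the lower share among its highest regions, and replicate 1 lay above the other two. The share of IDR summits rose to 0.334% without replicate 3 and to 0.326% among the stronger 1842 peaks. With a promoter window of 250 bp, promoters held 35.8% of IDR summits and introns 42.6%. At 500 bp introns held 37.8% of IDR summits and 34.4% of lower-ranked ones, intergenic sequence 14.4% and 18.7%, 3' UTRs 0.733% and 2.92%, 5' UTRs 0.461% and 1.29%, and other exons 1.85% and 2.11%. The intron share of the replicates, 36.7% ± 2.15 (SD, n = 3), differed from that of their lower-ranked regions, 36.3% ± 1.48, by less than the spread between replicates. These class shares other than the promoter share were described without a test.

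**Figure D2:**
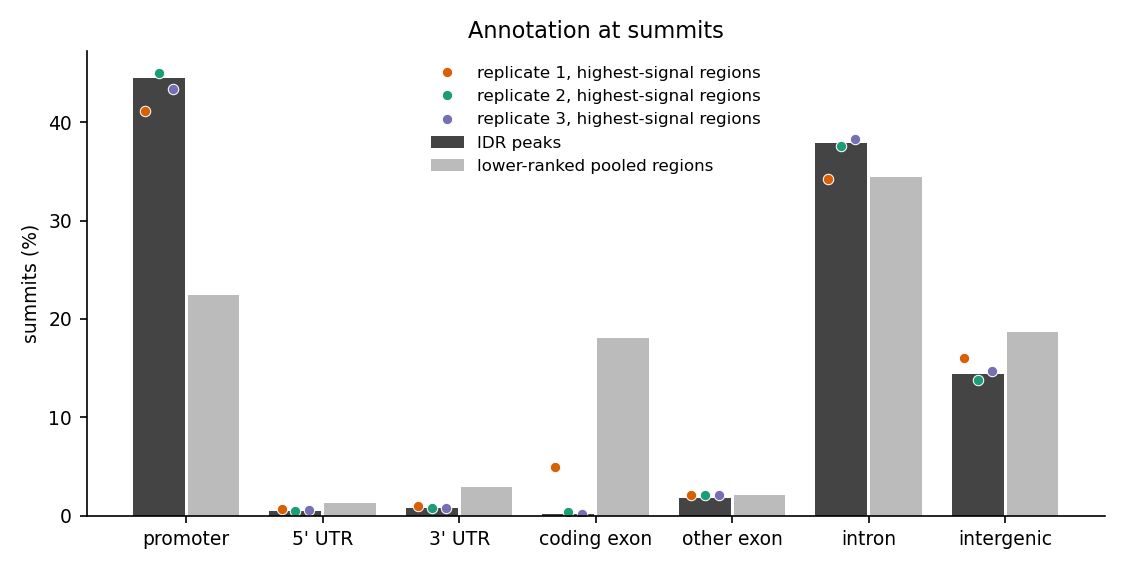
Share of summits (y axis, %) in each annotation class for the 3684 IDR peaks (dark bars) and the 20865 lower-ranked pooled regions (light bars), with the highest-signal regions of each replicate as points. Coding exons hold 0.19% of IDR summits and 18.1% of lower-ranked ones, and replicate 1 stands at 5.0%.

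A total of 2094 protein-coding genes (15.0% of 13945) had an IDR summit within 500 bp of a start site, and the replicates gave 1985, 2138 and 2005 genes, a mean of 2043 ± 83.2 (SD, n = 3). Of the 23 gene lists, 2 were occupied more often than the other genes, 3 less often, and 18 did not pass the test. The 3 less often include the replication-dependent histones, whose genes had no region of any rank in the pooled list, and their result is not read as a difference.

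Genes for cytosolic ribosomal proteins, the components of the cytoplasmic ribosome, stood far above all other lists. An IDR summit was present at 65 of 93 of them (69.9%), against 14.7% of the other genes, with an odds ratio of 13.5 (95% interval 8.66 to 21.1, Fisher's exact test, adjusted p = 1.73e-31). The replicates gave 64.5%, 67.7% and 62.4%, a mean of 64.9% ± 2.71 (SD, n = 3). These genes were served by 71 separate IDR summits. The strongest were at RpL7 (signal value 714.5), RpS27 (669.5), RpL32 (508.4) and RpL34b (503.9). Translation factors, which here include the aminoacyl-tRNA synthetases, were occupied at 21 of 68 genes (30.9%, odds ratio 2.54, 95% interval 1.52 to 4.27, Fisher's exact test, adjusted p = 0.00412), with 29.9% ± 2.25 (SD, n = 3) in the replicates. Examples were eIF6 (649.1), eEF1gamma (524.5), eIF1 (332.0) and SerRS (312.2). eIF1 has the arm and signal value of the ribosomal protein gene RpL28, so the pair may share a peak. The call of translation factors ended among the stronger 1842 IDR peaks (Fisher's exact test, adjusted p = 0.0569) and when replicate 2 was left out (adjusted p = 0.0679).

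The other lists occupied less often were chemosensory receptors, at 1 of 176 genes (0.568%, odds ratio 0.0319, Fisher's exact test, adjusted p = 1.83e-10), and cuticle proteins, at 1 of 117 (0.855%, odds ratio 0.0483, adjusted p = 9.58e-07 in the same test). The single occupied members were Ir60e (121.1) and Cpr65Av (100.6). The replicates gave 0.758% ± 0.328 for the receptors and 1.42% ± 1.78 for the cuticle genes (SD, n = 3). Regions of any rank in the pooled list were also few within 500 bp of these genes, at 15 of 176 receptor genes and 23 of 117 cuticle genes, against 6283 of 13945 protein-coding genes. The lower shares are therefore in part a lack of any region, and the lists do not show how far these genes could be measured. Of the 111 histone genes, which lie in a tandem repeated cluster, 0 had such a region. Their 0 IDR summits therefore do not show whether the protein was absent there.

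The lists closest to the known partners of Chiffon did not pass the test. DNA replication genes were occupied at 8 of 42 (19.0%, odds ratio 1.33, 95% interval 0.616 to 2.88, Fisher's exact test, adjusted p = 0.787), with 22.2% ± 5.99 (SD, n = 3) in the replicates. The 8 were dpa, which encodes the helicase subunit Mcm4 (signal value 241.7), dup, the fly Cdt1 gene (230.9), Ctf4 (177.8), PolA1 (149.4), Prim1 (146.2), Psf1 (143.6), Cdc7 (142.8) and PolD2 (140.5). SAGA and ATAC subunits were occupied at 5 of 27 (18.5%, odds ratio 1.29, 95% interval 0.487 to 3.40, Fisher's exact test, adjusted p = 0.797), namely Gcn5 (208.1), Ada2b (202.6), Ada3 (181.8), e(y)2 (105.5) and Sgf29 (101.6). PolA1, Psf1 and Sgf29 have the arm and signal value of mRpL47, Sf3b6 and RpL29 in that order, so each may share a peak. Cell cycle regulators gave 10 of 41 (24.4%, adjusted p = 0.307 in Fisher's exact test), led by Dp (296.9), Bub3 (197.4), aurA (186.1) and SMC2 (173.3). Genes for chorion and vitelline membrane proteins, which follicle cells of the ovary express, gave 0 of 14 (adjusted p = 0.441 in Fisher's exact test).

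Among the other housekeeping lists, insulator and housekeeping promoter factors reached 8 of 24 (33.3%) and did not pass the adjusted test (Fisher's exact test, p = 0.0199, adjusted p = 0.0763), with Chro (1409), Dref (274.0), Cp190 (265.9) and Trl (261.8) the strongest. Dref has the arm and signal value of the ribosomal protein gene RpL13, so the pair may share a peak. Mitochondrial ribosomal proteins were occupied at 15 of 73 (20.5%), among them mRpL41 (1406), mRpS10 (1388), mRpS23 (1186) and mRpL23 (575.0). The mRpS10 and mRpS23 peaks are those named above for Art3 and CenG1A, whose promoters they share. Proteasome subunits gave 7 of 32 (21.9%, led by Rpn5 at 321.8), oxidative phosphorylation 11 of 71 (15.5%, led by ND-MWFE at 395.1), splicing factors 5 of 34 (14.7%, led by SF2 at 184.4) and heat shock proteins 3 of 16 (18.8%), which were Hsp83 (335.3), Hsp27 (303.3) and Hsp26 (252.5). Adjusted p-values of these lists lay at 0.419 or above by Fisher's exact test.

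None of the patterning, signalling and tissue lists passed the test, and their shares lay on both sides of the 15.0% of all protein-coding genes. Hox and segmentation genes that matched the annotation were occupied at 1 of 37 (2.70%, odds ratio 0.157, Fisher's exact test, p = 0.0351, adjusted p = 0.115), and that gene was bcd (187.0). The listed symbol nos did not match, because the annotation names that gene nanos. It carried an IDR summit (116.3), so the share and the test leave out an occupied member of the planned list. The measured share of the list was 2.70% in each replicate. Neuronal genes gave 2 of 25 (8%), elav (499.7) and scrt (135.0), hemocyte genes 0 of 14, tracheal genes 1 of 10 (bnl, 92.9), early zygotic cellularization genes 2 of 15 (Sxl, 181.0, and comm, 97.4) and muscle genes 3 of 21 (Msp300, 627.0, sls, 331.3, and tin, 116.8). Signalling components gave 7 of 30 (23.3%, led by spi at 479.7) and germline genes 5 of 15 (33.3%, led by bgcn at 263.5, and including piwi at 118.6 and nanos at 116.3). The germline share ranged from 13.3% in replicate 1 to 33.3% in replicate 3.

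**Figure D3:**
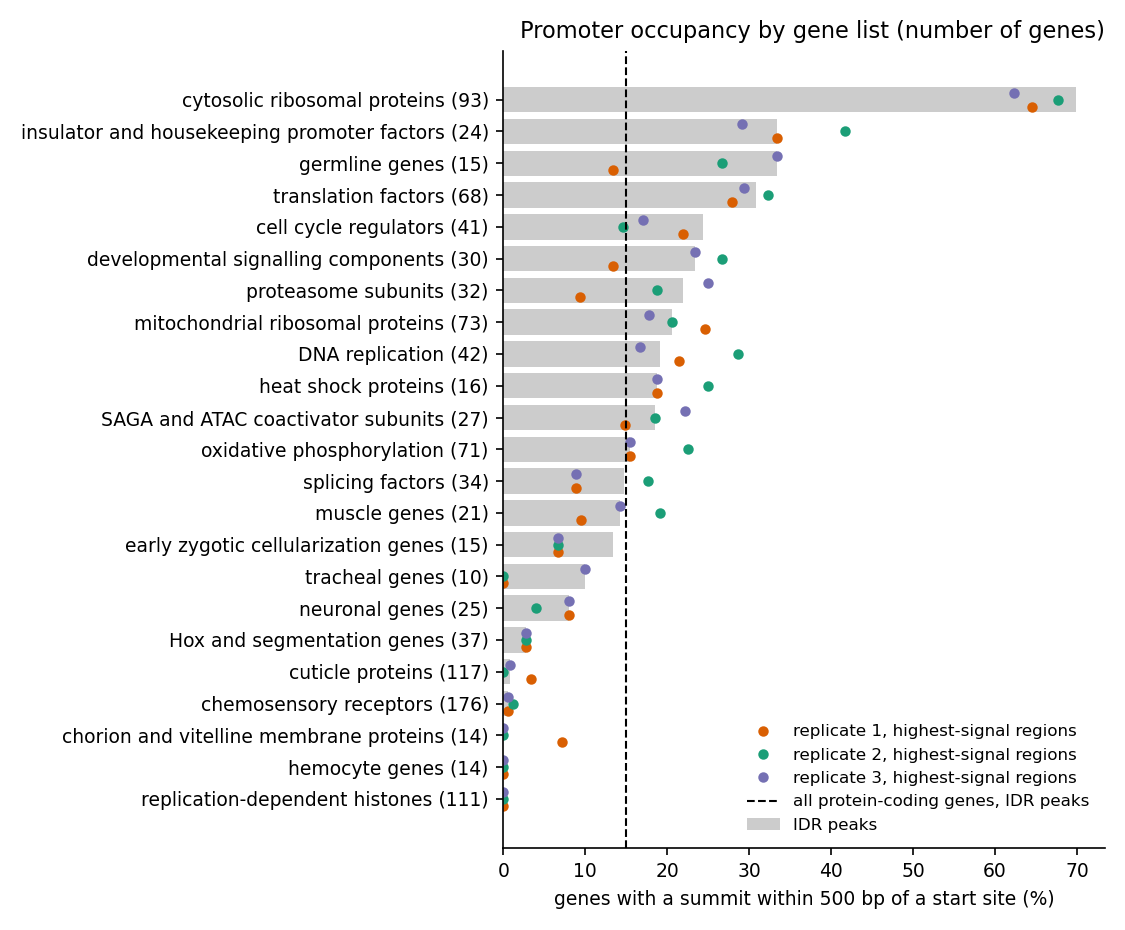
Share of genes with a summit within 500 bp of a start site (x axis, %) for each of 23 gene lists, with the number of genes in brackets. Bars are IDR peaks, points the 3684 highest regions of each replicate, and the dashed line the share over all protein-coding genes, 15.0%. Cytosolic ribosomal protein genes, at 69.9%, stand above every other list in all 3 replicates.

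Genes classed as head to head carried peaks more often than the rest. Of 3878 genes with a start site of another gene on the opposite strand within 500 bp, 1136 (29.3%) were occupied, against 958 of 10067 others (9.52%), an odds ratio of 3.94 (95% interval 3.58 to 4.34, Fisher's exact test, p = 3.52e-171). The replicates gave 28.8% ± 1.60 and 9.21% ± 0.380 (SD, n = 3), and each showed the same direction. A peak between such a pair counts for both genes. With each peak assigned to its nearest start site alone the odds ratio was 1.96 (Fisher's exact test, p = 7.09e-32).

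Peaks were spread over the large chromosome arms in similar density, and X promoters were occupied slightly less often. Density was 28.9 IDR peaks per Mb on X and 26.6 to 30.2 on 2L, 2R, 3L and 3R, with 8.16 per Mb (11 peaks) on chromosome 4. Lower-ranked regions were fewer on X, at 130.4 per Mb, than on these 4 arms, at 150.8 to 172.2 per Mb. On X, 297 of 2196 protein-coding genes (13.5%) were occupied, against 1793 of 11669 on the autosome arms (15.4%), an odds ratio of 0.861 (95% interval 0.755 to 0.983, Fisher's exact test, p = 0.0271). The odds ratio was 0.901, 0.831 and 0.777 in replicates 1, 2 and 3, and replicate 1 did not pass the test (Fisher's exact test, p = 0.127). The call ended with a window of 1000 bp (odds ratio 0.942, Fisher's exact test, p = 0.344) and when replicate 3 was left out (0.888, p = 0.122 in the same test). On chromosome 4, 4 of 80 genes were occupied (5%).

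Sequence at the summits differed in base composition, and most motif calls were lost against a background matched in GC content. Windows reaching 100 bp either side of IDR summits had a mean GC content of 36.8%, against 45.7% at lower-ranked summits and 42.2% at random positions, a comparison added after seeing the data. The highest regions of the replicates had 40.1%, 36.7% and 37.2%, a mean of 37.97% ± 1.84 (SD, n = 3), and their lower-ranked regions 45.2% ± 2.61. At IDR peaks over 1000 bp from start sites the GC content fell from 44.3% at -210 bp to 33.1% at the summit.

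Of 13 motifs, 5 were more frequent and 4 less frequent at IDR summits than at lower-ranked summits. This comparison was not split by promoter, and promoters held 44.5% of IDR summits against 22.5% of lower-ranked ones. It therefore does not separate motif differences of the peaks from their higher promoter share. The DRE, the site of the replication-related factor DREF (TATCGATA), was present at 3.37% against 1.40% (odds ratio 2.45, Fisher's exact test, adjusted p = 5.82e-14), with 3.40% ± 0.228 (SD, n = 3) in the replicates. Ohler motif 1, the M1BP site, was present at 1.19% against 0.566% (odds ratio 2.13), the Ohler motif 5 E-box at 1.11% against 0.542% (2.07), the TATA box at 4.21% against 2.41% (1.78) and the initiator at 44.8% against 37.6% (1.34). The Snail-type E-box was less frequent, at 5.56% against 9.51% (odds ratio 0.561, Fisher's exact test, adjusted p = 2.31e-15), as were the Zelda site, bound by the activator of the early zygotic genome, at 0.841% against 1.40% (0.598), the CA repeat at 3.28% against 4.97% (0.650) and the Pho site of the Polycomb recruiter at 7.63% against 9.64% (0.774). These 9 motifs had the same direction in all 3 replicates. The calls of the DRE, the TATA box, the initiator and the Snail-type E-box held with the other windows, among the stronger 1842 peaks and with each replicate left out, and the others did not all hold. The M1BP site lost its call with any 1 replicate left out (odds ratios 1.46, 1.20 and 1.46 without replicates 1, 2 and 3), among the stronger peaks (1.44) and with windows of 50 bp either side (1.21). The Ohler motif 5 E-box lost it without replicate 2 (Fisher's exact test, adjusted p = 0.0534). The Pho site lost it without replicate 2 (adjusted p = 0.132, Fisher's exact test) and among the stronger peaks (adjusted p = 0.102). The Zelda site lost it among the stronger peaks (adjusted p = 0.135, Fisher's exact test) and with 200 bp either side (adjusted p = 0.0511), and the CA repeat with 200 bp either side (odds ratio 1.03).

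The GAGA repeat (3.26% and 3.37%), the Twist-type E-box (14.4% and 14.9%), Ohler motif 6 (0.543% and 0.316%) and the E2F site (3.61% and 4.27%) did not pass the test. The GAGA repeat had an odds ratio of 0.964 over IDR peaks but of 1.35, 1.19 and 1.20 in replicates 1, 2 and 3. It was less frequent with windows of 50 bp either side (0.638, Fisher's exact test, adjusted p = 0.00886) and more frequent with 200 bp (1.83, adjusted p = 2.05e-21 in the same test). The E2F site passed as less frequent among the stronger peaks (0.664, Fisher's exact test, adjusted p = 0.00736), without replicate 1 (0.729) and without replicate 2 (0.731), and Ohler motif 6 as more frequent with 200 bp either side (1.80, Fisher's exact test, adjusted p = 0.00272). Against lower-ranked regions of matched GC content, an alternative chosen after seeing the data, only the CA repeat passed (odds ratio 0.665, Fisher's exact test, adjusted p = 0.00981), and the DRE did not (odds ratio 1.46, adjusted p = 0.0613 by Fisher's exact test). That comparison used 3684 matched pairs, against 20865 regions in the main background, so smaller numbers may contribute to the lost calls. The odds ratios of the other called motifs also moved towards 1 or past it. IDR promoter summits were also set against promoters with no IDR summit. Those promoter windows were centred on the start site and the IDR windows on summits mostly upstream of it, so the 2 sets differ by construction and no motif difference is read from them.

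**Figure D4:**
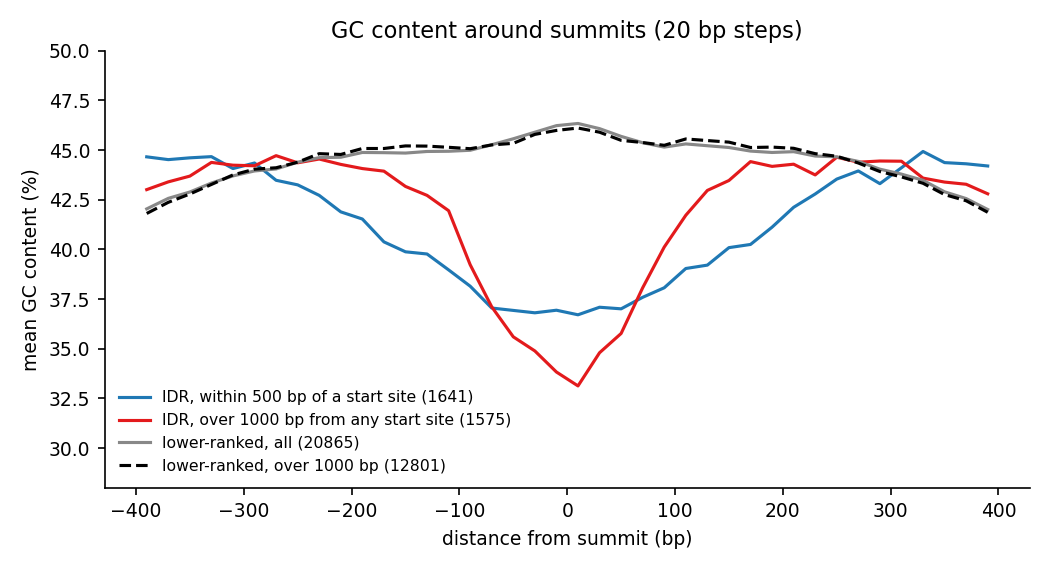
Mean GC content (y axis, %) in steps of 20 bp around summits (x axis, distance in bp) for IDR peaks within 500 bp of a start site, IDR peaks over 1000 bp from any start site, and lower-ranked regions. The profile of the 1575 distant IDR peaks reaches 33.1% at the summit, while the lower-ranked regions have no dip. The y axis does not start at 0.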

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

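The dm3 relaxed lists, of which only region numbers were used, also hold regions on heterochromatic and unplaced sequences outside the 6 chromosome arms. There were 435 such regions in replicate 1, 40 in replicate 2 and 35 in replicate 3. These sequences enter none of the comparisons, and the counts were not tested. The pooled dm3 list held 32 of them and the dm3 IDR list 0, and the dm6 lists hold regions on the arms alone.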

How the results depend on the processing

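No paired analysis was possible because there is 1 group. The alternatives were chosen before the data were examined, except the background of matched GC content and, for annotation classes, the left-out replicates. The promoter share, the head-to-head arrangement and the replicate overlap kept their direction and their side of the threshold under every alternative run. Their values ranged from 2.16 to 6.22 and from 1.96 to 4.48 as odds ratios, and from 56.2% to 75.2% as overlap. The number of gene lists past the threshold was 4 or 5 under every alternative, the unmeasured histones included, and the 2 losses were both of translation factors. The exon share of summits lay between 2.66% and 4.07%, but of 42 values of single classes 20 moved by more than the spread between replicates. Within 250 and 1000 bp the promoter share was 35.8% and 53.4%, the intron share 42.6% and 31.4%, the intergenic share 17.5% and 12.6%, and the 5' UTR share 0.869% and 0.0271%. A wider promoter window takes summits from the other classes by definition. The coding exon share was 0.334% without replicate 3, against 0.19%. The signal values and lists carry no depth, so what depth limits could not be examined.

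The share of IDR peaks found in all replicates was 50.2% with an overlap of 50% of both regions, 52.2% with summits within 100 bp, 93.7% among the stronger 1842 peaks, and 64.1% to 72.8% when a replicate was left out, where fewer replicates must agree. The odds ratio of X against the autosome arms was 0.942 within 1000 bp, and 0.789 to 0.888 when a replicate was left out. The number of motifs past the threshold was 1 with matched GC content and 5 against promoters with no IDR summit. Of these 5, only the Zelda site (0.438) had kept its call and direction. The TATA box, the initiator and Ohler motif 1 turned, the Twist-type E-box was gained, and the DRE lost its call (1.01). In that alternative the windows are centred differently, on start sites and on summits, so no motif difference is read from it. The cause was not tested for the other values.

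Of 161 values of single gene lists under alternatives, 20 crossed an odds ratio of 1, all for lists that had not passed the test. With the nearest start site alone these were DNA replication (0.863), early zygotic cellularization (1.26), muscle (1.37) and oxidative phosphorylation (0.896). Among the stronger 1842 peaks they were signalling (0.756), germline (0.756), muscle (1.11) and proteasome (0.706). Within 250 bp they were signalling (0.528) and splicing (1.28), and within 1000 bp early zygotic cellularization (1.17). When a replicate was left out, the odds ratio ranged from 0.964 to 1.48 for SAGA and ATAC, 0.834 to 1.46 for cell cycle, 0.946 to 1.54 for signalling, 0.569 to 1.93 for germline, 0.839 to 1.29 for muscle, 0.931 to 1.31 for oxidative phosphorylation and 0.531 to 1.10 for proteasome genes. The cause was not tested.

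Of 104 values of single motifs, 19 kept their direction but lost the call, 5 gained one and 20 crossed an odds ratio of 1. With windows of 200 bp either side those that crossed were the CA repeat (1.03), the GAGA repeat (1.83) and the Twist-type E-box (1.01). Against promoters with no IDR summit they were the GAGA repeat (1.07), Ohler motifs 1 (0.672), 5 (0.810) and 6 (0.671), the TATA box (0.477), the Twist-type E-box (1.37) and the initiator (0.645). With matched GC content they were the E2F site (1.18), the GAGA repeat (1.43), Ohler motif 6 (0.832), the Snail-type E-box (1.07), the Zelda site (1.19) and the initiator (0.967). The GAGA repeat stood at 1.01 among the stronger 1842 peaks. When a replicate was left out, the GAGA repeat ranged from 0.996 to 1.14 and the Twist-type E-box from 0.939 to 1.02. The cause was not tested.

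With a replicate left out, none of the 75 values of named peaks stood below the strongest 1.90% of its list. These lists hold 2681, 2312 and 2393 regions without replicates 1, 2 and 3, against 3684, so list length alone raises the percentile of a peak and no movement is read from it.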

Other observations

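All tests in this part were chosen after the results were seen. Most classes of genes that do not code for protein had lower shares of occupied members than the 15.0% of protein-coding genes, with the small nuclear RNA genes the exception. IDR summits lay within 500 bp of 165 of 3261 ncRNA genes (5.06%), 12 of 290 tRNA genes (4.14%, 95% Wilson interval 2.38 to 7.09), 11 of 269 snoRNA genes (4.09%), 2 of 268 pseudogenes (0.746%) and 0 of 99 rRNA genes. For snRNA genes the count was 6 of 32 (18.8%, interval 8.89 to 35.3), with 3.12% in replicate 1 and 18.8% in replicates 2 and 3. The rRNA genes had no region of any rank in the pooled list. Such regions lay by 838 of 3261 ncRNA, 77 of 290 tRNA, 75 of 269 snoRNA genes and 29 of 268 pseudogenes. For protein-coding genes the count was 6283 of 13945. The lower shares are therefore in part a lack of any region, and the lists do not show how far these genes could be measured.

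Low GC at the summits was weighed against 2 technical explanations. A single GC bias acting alike on all regions would place the lower-ranked regions below random positions too, and these had 45.7% GC against 42.2%. As the whole cause, a larger share of exons among lower-ranked summits would leave no difference in introns and intergenic sequence. IDR summits there had 36.2% against 42.3%, a smaller gap than the 36.8% against 45.7% over all summits. Exons may therefore account for part of the difference, but not for all of it. A bias that acts on the strongest regions alone, or a difference to the control library, which was not analysed here, remains open.

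A hypothesis is that many of the distant peaks mark short AT-rich elements with shared words at their edges. On 2L and 2R, words of 7 bases with at least 3 G or C were ranked by their excess within 150 bp of IDR summits over 1000 bp from start sites, against lower-ranked summits at the same distance. The leading word was CAGTGTA (reverse complement TACACTG). On 3L, 3R and X it was present at 165 of 1013 distant IDR summits (16.3%), against 5.35% of lower-ranked summits and 2.99% of random positions, an odds ratio of 3.45 (95% interval 2.84 to 4.18, Fisher's exact test, p = 3.67e-31), and its excess was the largest among 2240 words of the same GC content. The share was 14.2%, 14.2% and 15.3% in replicates 1, 2 and 3. Of its occurrences at IDR summits 65.8% lay 51 to 110 bp from the summit and 9.63% within 30 bp, against 39.96% and 20.5% at lower-ranked summits. On 2L and 2R the words ACTGAGA, CACTGAG, GAGAGAA and CTCTCAG came next. On 3L, 3R and X they had odds ratios of 2.35, 2.17, 2.13 and 2.26. Their places there were 6, 5, 10 and 8 among 2240 words of the same GC content. With CTCTCAG read as its reverse complement these later words are overlapping frames of 1 stretch of 11 bases, so they are not separate observations. The reverse complement of the leading word, TACACTG, ends in the bases CACTG with which CACTGAG begins. The leading word may therefore belong to the same stretch. CAGTGTA had been noticed on all arms before the arms were parted, so these data alone may overstate it.

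The occupancy of cytosolic ribosomal protein genes could reflect fragments recovered at strongly transcribed genes without the tagged protein. In the form that covers every strongly transcribed gene, tRNA genes would be occupied at least as often as protein-coding genes. An IDR summit was present at 4.14% of tRNA genes (upper limit 7.09%), against 15.0% of protein-coding genes. Regions of any rank in the pooled list were also fewer, at 77 of 290 tRNA genes against 6283 of 13945 protein-coding genes. The lists do not show how far tRNA genes could be measured, so their share does not decide this form. For mRNA genes alone the explanation cannot be told apart from binding. Oxidative phosphorylation genes stood at 15.5%, and neither expression levels nor an untagged control were analysed here.

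The strong peak in chif could be affected by extra copies of the gene carried by the transgene. An even rise over the gene would not set 1 region apart. In replicates 1, 2 and 3 the intron region had signal values of 296.1, 477.4 and 506.1. The next strongest region in chif had 80.37, 74.75 and 56.46. These values argue against an even rise as the whole cause of the peak. How far extra copies add to its height cannot be told. Regions of the pooled list covered 11.1% of the gene, against a median of 7.75% over 2471 protein-coding genes of 5 to 20 kb, 65.3% of which lay below chif. In the replicate lists the covered share was 20.1%, 14.8% and 19.1%. No value here shows how much of a gene a rise in copy number would bring into called regions, so this coverage decides nothing.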
